A study of Mus musculus with 2 samples.

How the data were processed

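Total RNA of regulatory T (Treg) cells from 5-week-old wild-type and Nr4a-TKO mice was hybridised to 1-colour Agilent mouse expression arrays, 1 array per genotype. Treg cells are CD4 T cells that restrain immune responses, and Nr4a1, Nr4a2 and Nr4a3 are related nuclear receptors. The labels name the genotype Nr4a-TKO without saying which part of which gene was altered. They do not give the sex of the mice, the number of mice behind each sample, or the sorting markers. The cells were lysed directly after sorting, per the labels' protocols. Samples were grouped by the genotype in the labels. Both arrays lay on 1 slide and carried 1 scan time, so genotype was not split by slide or scan.

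The authors deposited spot intensity values from Agilent Feature Extraction 10.10.1.1, per the file headers. Spatial and multiplicative detrending and surrogate values for dim spots were switched on, per the file headers, and no normalization between arrays was found in these intensities. The arrays were annotated on mm9, per the file headers, and all coordinates are given on that build. A second deposited table held log2 values for the same probes. Set against the scanner signals, these log2 values, whose scaling is not given in the sources used here, were the log2 processed signal less 1 constant per array, to within an SD of 0.00029 on each array. Their column medians were -3.54 for wild-type and -3.53 for Nr4a-TKO. Their constant lay near the 75th percentile, and the exact rule behind it stays unknown.

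Each array held 62976 spots, of which 3671 were controls. Control spots and spots flagged as non-uniform or population outliers (156 on the wild-type array and 117 on the other) were left out. Signals were taken as log2, averaged over the spots of a probe, and reduced by the array's 75th percentile over 55676 probes. Names came through transcript accessions for 27592 probes, matched to a RefSeq table of assembly GRCm38.p6 that was used for names only. The other 28084 probes kept the name in the file. A gene was represented by its probe with the highest mean signal. It was counted where that probe was well above background on both arrays in the scanner's own call, which 23492 gene names met. Where that probe was well above background on 1 array and no probe of the gene was so on the other, the difference was given as a lower bound. For Xist, bounds were also given for single probes. The bound set the bright array's value against the higher of 2 values on the dim array: the lowest signal among probes well above background there, and the probe's own signal.

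With 1 array per genotype the differences have no replicate check, and no p-value, standard error or test across genes was computed. Their number limits the precision. A size of 2-fold was used to count genes. For each of 28 gene lists the median log2 difference was taken over members well above background on both arrays. Its percentile was found among 10000 random lists of the same size matched on mean signal in 20 bins. This describes these arrays and tests nothing about the genotypes. A 95% binomial order-statistic interval is given for some of the medians. It treats members as independent draws, which genes on 1 pair of arrays need not be. It does not measure variation between mice, and below 6 members it spans only the lowest to the highest. The lists, the choice of scaling, the alternatives and the rule for named genes were fixed before the data were examined.

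Named genes followed 4 parts of a rule. Members of the Nr4a family, Treg signature, Th2 and Tfh lists could be named with a summary of the list. The 15 largest differences in each direction were named among genes well above background on both arrays, with a plain gene symbol and no probe of opposite direction. The 5 largest lower bounds in each direction were named, and up to 4 leading members of every other list. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen, as were 5 further lists used in the closing part.

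Technical error was described by the spread between spots of a probe, the Agilent spike-in controls and the agreement between probes of a gene. Alternatives were normexp background correction (offset 50) on mean and local background signals and scaling on the array median or on the 75th percentile of probes well above background. Others were quantile normalization, centring on spike-ins or on housekeeping genes, loess on signal (span 0.3), the deposited log2 table, the mean over probes, no filter or a stricter filter on dim probes, and thresholds of 1.5-fold and 3-fold. Counts without X and Y genes, and 3 list medians without their leading member, were added after seeing the data. The slide could not be a block with 1 array per genotype.

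Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The gene counting step was tested on simulated data made for the Nr4a-TKO against wild-type comparison over 23484 genes, with noise of SD 0.1. All 100 genes altered by 1.5 on the log2 scale and all 100 altered by 3 passed the 2-fold size, and 0 of 23284 unaltered genes did. The simulated noise left out the gaps between probes of a gene, whose 95th percentile was 1.16 on these arrays. These counts therefore check the arithmetic and give no rate of false calls for the arrays. The list step was checked on the measured differences of the 2 arrays, with fewer random draws than above. Of 200 lists of random genes, 9 fell outside the middle 95%, near the share set by construction. Of 50 lists of 15 random genes shifted by 0.5, 49 lay above the middle 95%. Neither count covers lists of genes that are regulated together.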

Results

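The series title links Nr4a to a Treg-specific transcriptional program and to restraint of Th2 and Tfh responses, the helper T cell types that drive type 2 immunity and help B cells. The arrays compared Treg cells sorted from wild-type and Nr4a-TKO mice, with 1 sample of each. On the wild-type array 36732 of 55676 probes (66.0%) were well above background, and on the other 35567 (63.9%). There are no replicates, so every difference below is between 2 arrays and not between genotypes tested with error. The scanner marked 0 spots as saturated on either array. Differences are log2 values of the array labelled Nr4a-TKO minus wild-type, after scaling each array to its 75th percentile.

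Of Nr4a1, Nr4a2 and Nr4a3, only Nr4a3 was lower in the array labelled Nr4a-TKO in the main setting, by 7.04-fold (log2 signal -1.11 in wild-type and -3.93 in the other), or 3.26-fold with normexp background correction. Its probe lies on chromosome 4, spans 48080690 to 48083876, and had 9 usable spots on each array. Nr4a1, on chromosome 15 at 101105071 to 101105130, differed by 0.06 on the log2 scale (6.90 and 6.96), a direction that turned under 4 of the scalings. Nr4a2 was higher by 2.54-fold at 56960699 to 56960758 on chromosome 2, and by 2.05-fold at a second probe at 56959637 to 56959696. The labels do not say which part of which gene was altered, and a probe outside an altered part checks nothing about it. Because the Nr4a1 and Nr4a2 signals were not lower, the genotype stands as a label, and every direction below is drawn from that label.

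Sex-linked transcripts also set the samples apart. All 7 probes of Xist, the RNA that silences 1 X chromosome in female cells, were brighter in the array labelled Nr4a-TKO. The 5 that were not well above background in wild-type gave bounds between at least 61.3-fold and at least 927-fold. The 2 measured on both arrays, which the file names XIST, gave 228-fold and 380-fold, and the brighter gave 160-fold with normexp. The Y-linked genes Ddx3y, Eif2s3y and Uty were lower by 3.63-fold, 1.97-fold and 1.52-fold, yet well above background on both arrays. A second Uty probe, also well above background on both, was lower by 2.71-fold. Kdm5d was at least 1.78-fold lower. The sex-linked list had 3 members measured on both arrays, all Y-linked, with a median of -0.98 (percentile 0.31).

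Among 23492 gene names measured on both arrays, 740 were at least 2-fold higher and 720 at least 2-fold lower in the array labelled Nr4a-TKO. For the 14115 plain gene symbols these counts were 578 and 381. A further 259 gene names were at least 2-fold higher and 227 at least 2-fold lower by their bounds. The median difference over all names was 0.08 and the SD 0.56. Without X and Y genes, a count added after seeing the data, 713 were higher and 690 lower. Centring on spike-ins shifted the median of all genes by -0.27 and gave 448 higher and 1250 lower, which is 26.4% higher against 50.7% in the main setting. Centring on housekeeping genes shifted it by -0.12 and gave 40.2% higher.

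**Figure D1:**
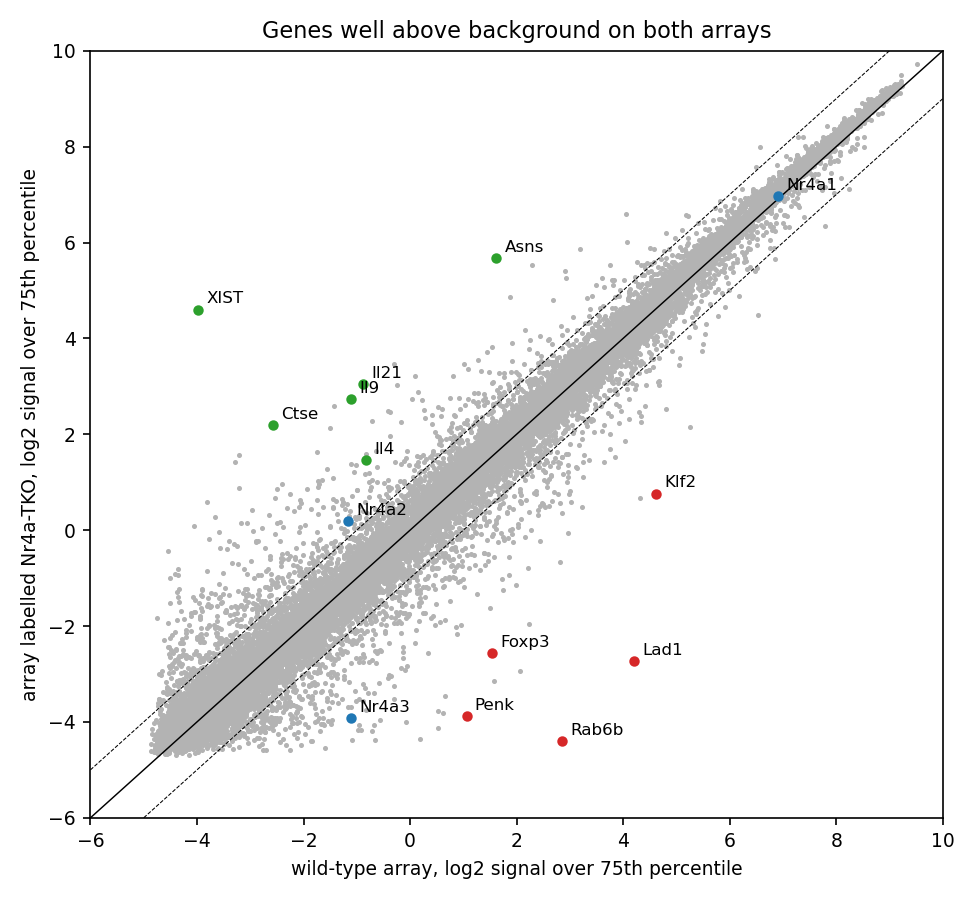
Each point is 1 of 23492 gene names well above background on both arrays, with the log2 signal over the 75th percentile in wild-type on the x axis and in the array labelled Nr4a-TKO on the y axis. The solid line marks equal signal and the dashed lines 2-fold, with Foxp3, Rab6b and Lad1 far below them and Il21, Il9 and Asns above.

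The largest differences in the lower direction included Foxp3, the transcription factor that defines Treg cells, at 17.2-fold. Its only probe lies on the X chromosome at 7172301 to 7172360. With normexp all 30 leading genes of both directions differed less, 20 of them by over 1.5 times, and Foxp3 was lower by 10.3-fold. Rab6b was lower by 152-fold, Lad1 by 122-fold, Adh1 by 32.1-fold and Penk, which encodes the enkephalin precursor, by 30.7-fold. With normexp these were 52.4-fold, 74.7-fold, 18.2-fold and 11.6-fold. The X-linked Xlr and Slx, members of multicopy families whose copies a probe may not separate, were lower by 23.2-fold and 21.5-fold, or 7.54-fold and 9.05-fold with normexp. Myo6 was lower by 18.2-fold, Klf2 by 14.5-fold, Tmem169 by 13.3-fold, Atp1b1 by 12.4-fold and Pdzk1ip1 by 11.2-fold. Nipal1, Cyp1a1 and Tnnt2 completed these 15 genes at 9.86-fold, 9.44-fold and 9.35-fold. With normexp Tmem169, Nipal1, Cyp1a1 and Tnnt2 were at 4.87-fold, 3.94-fold, 4.02-fold and 4.54-fold. By bounds, Pla2g4f was at least 32.7-fold lower, Pou6f1 at least 26.3-fold, Eps8l1 at least 25.4-fold, Agr3 at least 23.1-fold and Ifi211 at least 18.0-fold.

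In the higher direction, after XIST, stood Ctse and Serpinf1, each at 27.3-fold, Mgll at 25.9-fold and Sphk1, a sphingosine kinase, at 21.3-fold. Dclk1 was higher by 17.7-fold and Lratd1 by 17.0-fold. With normexp Ctse was at 17.9-fold, Serpinf1 at 14.8-fold, Mgll at 14.0-fold, Sphk1 at 9.64-fold, Dclk1 at 7.26-fold and Lratd1 at 9.45-fold. Asns, which makes asparagine, was higher by 16.7-fold, the amino acid transporter gene Slc7a3 by 16.2-fold and Chac1, which degrades glutathione, by 13.6-fold. The cytokine genes Il21 and Il9 were higher by 15.3-fold and 14.4-fold. Batf3 was higher by 12.6-fold and Fut10 by 12.0-fold, the latter at 6.03-fold with normexp. As the mean of their probes, Serpinf1 was at 11.1-fold, Dclk1 at 10.3-fold and Fut10 at 6.16-fold. By bounds, Rpl39l was at least 34.5-fold higher, Actc1 at least 17.0-fold, Opn1sw at least 14.5-fold and Inhba at least 13.3-fold.

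In the Treg signature, 26 of 30 members were measured on both arrays, with 6 at least 2-fold lower, 3 at least 2-fold higher and 17 between. Besides Foxp3, the lower members were Gzmb (5.61-fold), Ikzf2 (3.07-fold), Ctla4, an inhibitory receptor (2.29-fold), Ikzf4 (2.13-fold) and Swap70 (2.11-fold). Plagl1 was higher by 7.97-fold, Nrp1 by 3.23-fold and Ebi3 by 2.08-fold. The 4 probes of Plagl1 ranged from 0.43 to 3.04 on the log2 scale, and their mean gave 3.39-fold. Ikzf4 and Ebi3 came under 2-fold in some settings. The IL-2 receptor genes Il2ra and Il2rb differed by -0.39 and 0.22, Tnfrsf18 by -0.56, Lrrc32 by -0.45 and Gpr83 by 0.20, and the direction of Il2rb and Gpr83 turned under some scalings. The list median was -0.29 (95% interval -0.78 to 0.22), below all 10000 matched random lists, and -0.23 without Foxp3, a setting added after seeing the data. T cell identity genes (-0.52) and genes lower in Treg than in conventional CD4 T cells (-0.38) also had medians below all random lists. A low median was therefore not particular to the Treg signature.

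In the Th2 list, 16 of 22 members were measured on both arrays, with 4 at least 2-fold higher, 2 at least 2-fold lower and 10 between. The cytokine genes were higher: Il9 as above, Il4 by 4.91-fold, Il13 by 3.36-fold and Il24 by 3.03-fold, of which Il24 was at 1.96-fold with normexp. The Th2 transcription factor gene Gata3 was lower by 3.54-fold and the chemokine receptor gene Ccr8 by 4.40-fold. Il5, Il6, Il31, Il1rl1 and Areg were not well above background on either array, and Il17rb was at least 3.03-fold lower. The list median was 0.40 (95% interval -0.16 to 1.60), at the 99.96th percentile. It did not stand apart without the filter on dim probes (0.19, percentile 90.9) or with the stricter filter (0.067, percentile 42.7).

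In the Tfh list, 19 of 20 members were measured on both arrays, with 2 at least 2-fold higher, 2 at least 2-fold lower and 15 between. Il21 and Il4, which Tfh cells secrete to help B cells, were the higher members, and Il4 is among the 2 genes shared with the Th2 list. Sh2d1a was lower by 2.97-fold and Tox by 2.05-fold, of which Tox came under 2-fold in 1 setting. Bcl6, the Tfh transcription factor gene, differed by 0.73, Pdcd1 by 0.51, Icos by 0.60 and Cd200 by 0.93. Cxcr5, the receptor that leads cells into follicles, differed by 0.04, with a direction that turned under some scalings. The list median was 0.57 (95% interval -0.03 to 0.82), above all 10000 matched random lists. Th17 genes (1.24), effector Treg and activation genes (0.48) and proliferation genes (0.55) also had medians above all random lists. A high median was therefore not particular to the Tfh list. The B cell marker list had a median of 0.08 (percentile 55.3).

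**Figure D2:**
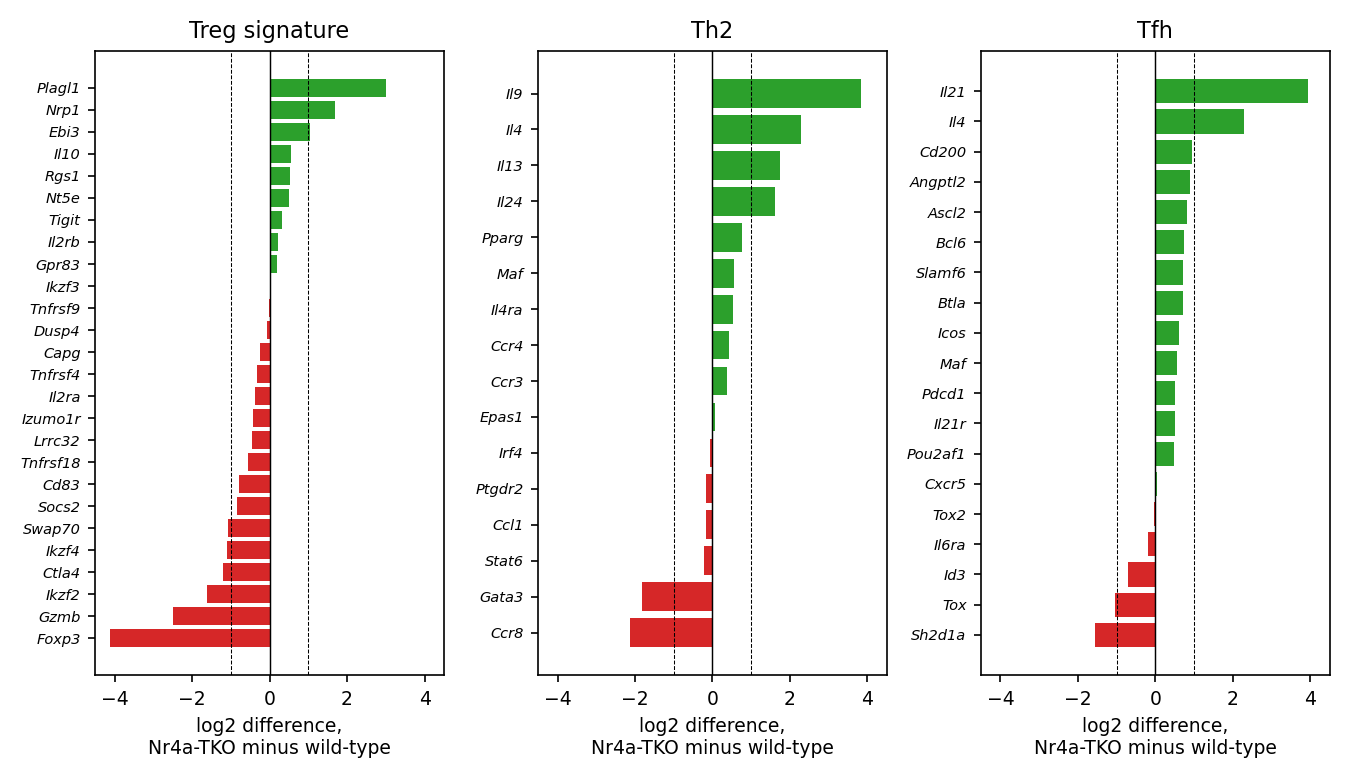
Bars give the log2 difference, Nr4a-TKO minus wild-type, of each member of the Treg signature, Th2 and Tfh lists well above background on both arrays, with dashed lines at 2-fold. Foxp3 has the longest bar to the left among Treg genes at -4.11, and Il9 (3.85) and Il21 (3.94) the longest to the right in the Th2 and Tfh lists; the short bars of Il2rb, Gpr83, Ikzf3, Ccl1, Epas1, Cxcr5 and Tox2 change side under some scalings.

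Genes of other helper programs differed in direction. In the Th17 list 7 of 11 measured members were at least 2-fold higher and 0 lower, with a median of 1.24 above all random lists. Il21, Il1r1 (6.31-fold, or 3.30-fold with normexp) and Il17f (2.96-fold) were also among the 7, while Il17a was at least 14.6-fold lower. The Th1 median was -0.29 (percentile 0.95) over 13 members. Cxcr3 was higher there by 7.20-fold and Eomes by 2.47-fold, and Ifng was lower by 3.91-fold and Ccl3 by 2.35-fold, of which Eomes and Ccl3 came under 2-fold in some settings. The Th1 median did not stand apart without the filter on dim probes (0.079, percentile 65.4), with the stricter filter (-0.060, percentile 20.1) or with the mean of probes (-0.16, percentile 4.32).

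Genes of naive and resting T cells were mostly lower, with 7 of 16 members at least 2-fold lower, 1 higher and a median of -0.56 below all random lists. Klf2, S1pr1, which guides exit from lymphoid tissue (4.68-fold), and Klf3 (4.12-fold) were lower, and Ly6c1 was higher by 5.82-fold at its brighter probe and differed by 0.015 on the log2 scale at the other. Chemokine receptors and homing genes had a median of -0.60 (95% interval -1.28 to 0.43), also below all random lists. Itga4 was lower by 4.78-fold there (3.13-fold as the mean of 2 probes), S1pr1 and Ccr8 as above, and Cxcr3 was higher. Genes lower in Treg than in conventional CD4 T cells had a median of -0.38 (95% interval -0.88 to 0.21), below all random lists, and share 8 genes with the naive list. St8sia1 (4.04-fold), Vipr1 (2.52-fold, with a second probe at -0.27) and Bach2 (2.14-fold) were lower, and Themis was higher by 3.19-fold. T cell identity genes had a median of -0.52 below all random lists, with Trat1 lower by 4.15-fold, Cd27 by 3.61-fold and Cd2 at -0.59.

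Genes of effector Treg cells and activation had a median of 0.48, above all random lists, with 5 of 22 members at least 2-fold higher and 1 lower. Cxcr3, Ahnak (4.83-fold, with 4 probes from 0.37 to 2.27 on the log2 scale) and Id2 (3.25-fold) were higher and Gzmb was lower. All 25 proliferation genes were measured, with 7 at least 2-fold higher, 0 lower and a median of 0.55 above all random lists. Ccnb1 (2.88-fold), Ccnb2 (2.58-fold), Cdc20 (2.46-fold) and Aurka (2.32-fold) led them. Aurka came under 2-fold in some settings, as did the other higher members Bub1b, Plk1 and Cenpf. Of the 25 genes 23 were higher by any amount and 2 lower, Tyms at -0.26 and Mcm3 at -0.33. A further Mcm3 probe was at 0.61. Pcna, Mcm2, Mcm5 and Mcm6 differed by only 0.01, 0.12, 0.16 and 0.17, and their direction turned under some scalings.

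Other programs differed less. The TCR immediate-early median was -0.04 (percentile 2.69, and as low as 0.10 with quantile normalization), with Ier3 higher by 5.05-fold, Atf3 by 3.94-fold, and Dusp5 lower by 3.98-fold and Dusp1 by 1.96-fold. The apoptosis and survival median was -0.11 (percentile 1.29, and up to 4.96 with quantile normalization), and Fasl, a death ligand, was lower by 4.69-fold, with Mcl1 at -0.65, Bcl2 at -0.60 and Bak1 at 0.48. The interferon-stimulated median was -0.05 (percentile 8.66), with Ifit3 lower by 6.33-fold (4.05-fold with normexp) and Isg15 higher by 2.75-fold, Oasl1 by 2.49-fold and Oas1a by 2.37-fold. Oasl1 and Oas1a came under 2-fold in some settings. TGF-beta and IL-2 signalling genes had a median of -0.18 (percentile 0.04) and 0 members past 2-fold, with Skil at -0.92, Socs2 at -0.84, Tgfbr2 at -0.75 and Stat5a at 0.66. The glycolysis median was 0.26 (percentile 95.4, and up to 99.3 with the mean of probes), the heat shock and handling stress median 0.28 (percentile 92.3) and the housekeeping median 0.12 (percentile 24.0), with 0 members past 2-fold in each. The glycolysis and housekeeping medians came below 0 with spike-ins as the centre.

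The medians of markers of other cell types the sort could hold lay within the middle 95% of matched random lists in the main setting. They cover only markers measured on both arrays, so they cannot exclude a cell type whose markers appear on 1 array. Markers well above background on 1 array only numbered 3 for macrophages and dendritic cells and 2 for erythroid cells and platelets. There was 1 each for B cells, CD8 and NK cells, and epithelial and stromal cells. By bounds, 1 CD8 and NK marker and 1 erythroid and platelet marker were at least 2-fold lower. An epithelial and stromal marker was at least 2-fold higher. Medians were -0.04 for plasma cells (percentile 18.9), -0.13 for CD8 and NK cells (14.6), -0.06 for macrophages and dendritic cells (11.4) and -0.14 for granulocytes and mast cells (19.99). They were -0.31 for erythroid cells and platelets (5.52), 0.00 for immature thymocytes (29.7) and -0.18 for epithelial and stromal cells (11.2). Of 16 granulocyte and mast cell markers only 4 were measured on both arrays, 7 were well above background on 1 array only, and 4 of these were at least 2-fold lower by their bounds with 0 higher. Without the filter on dim probes this list had a median of -0.35 (percentile 0.10), and with the stricter filter CD8 and NK cell markers had a median of -0.65 (percentile 1.08). Single members went further, such as Mpo, a granulocyte gene, lower by 7.76-fold, Lyz1 lower by 4.20-fold, Gzma higher by 3.44-fold and Sdc1 higher by 3.17-fold. With normexp these were 3.04-fold, 1.89-fold, 2.19-fold and 2.01-fold. Among B cell markers, Cd72 was lower by 3.95-fold and H2-Ab1 and Cd79b were higher by 2.59-fold and 2.51-fold.

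**Figure D3:**
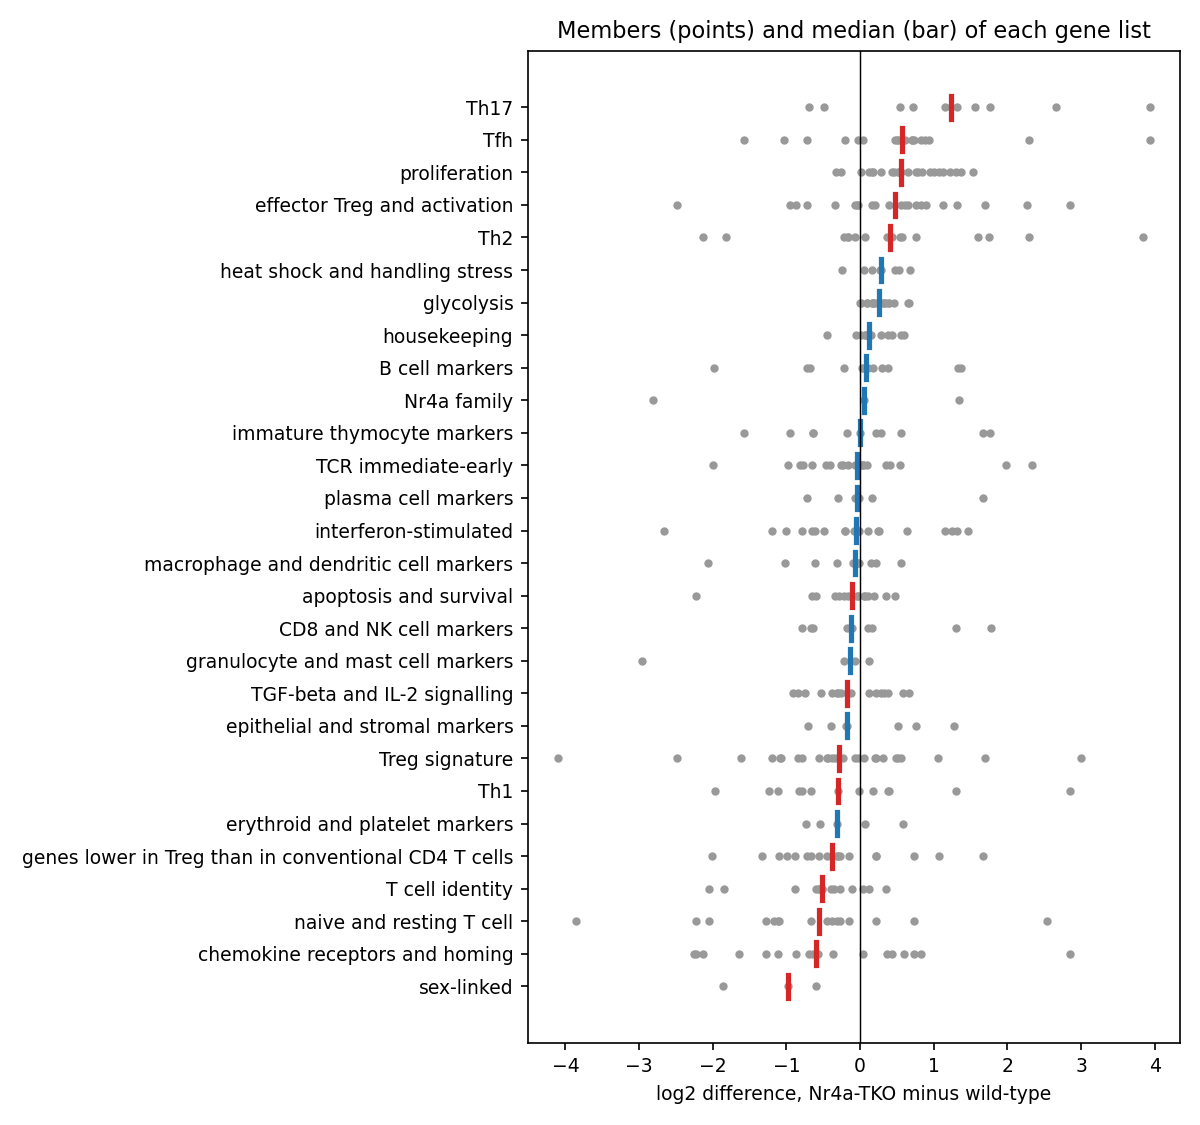
Grey points give the log2 difference, Nr4a-TKO minus wild-type, of each measured member of the 28 lists, and bars the list median, red where it lies outside the middle 95% of matched random lists and blue otherwise. Th17 (1.24) lies highest and the sex-linked list (-0.98) lowest; with spike-ins as the centre all points shift by -0.27, which turns the positive medians nearer to 0 than that.

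The SD between spots of 1 probe had a median of 0.061 in wild-type and 0.051 in the other array over 262 probes, which gives 0.080 for a difference. Spike-in controls differed by 0.27 after scaling, with a range of 0.02 to 0.31 over 9 probes. Of 393 genes past 2-fold with several measured probes, 316 had all of them in 1 direction. Over 6748 genes with several measured probes, the largest gap between probes of a gene had a median of 0.25 and a 95th percentile of 1.16 on the log2 scale. These spreads hold no variation between mice or preparations.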

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

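The settings without X and Y genes or without 1 leading member were chosen after seeing the data. The 740 higher and 720 lower genes became 477 and 457 with normexp, 448 and 1250 with spike-ins as the centre, 1986 and 1834 without the filter on dim probes, 331 and 362 with the stricter filter, 1964 and 1728 at 1.5-fold and 288 and 283 at 3-fold. The filter and threshold counts move by construction. So do the spike-in counts, since that centring shifts every gene by -0.27. The normexp setting adds a fixed offset to the signals, which by construction makes the differences of dim genes smaller. How much its background step also moved the counts was not tested. Without X and Y genes they were 713 and 690. The Treg signature, Th2 and Tfh medians kept their sign in every setting run. The Th2 median was 0.067 (percentile 42.7) with the stricter filter and 0.19 (percentile 90.9) without the filter, so it stood apart in neither. The 3 medians were -0.23 without Foxp3, 0.37 without Il9 and 0.54 without Il21. The Th1 median reversed to 0.079 without the filter on dim probes, and the cause was not tested. Centring on spike-ins moved the medians to 0.28 for proliferation, -0.38 for apoptosis and survival, -0.45 for TGF-beta and IL-2 signalling, -0.018 for glycolysis, -0.79 for T cell identity and -0.16 for housekeeping, a shift of -0.27 on all genes. Loess moved proliferation to 0.43, glycolysis to 0.085, T cell identity to -0.63 and housekeeping to -0.033. T cell identity was -0.62 with quantile normalization and -0.63 with housekeeping centring. Housekeeping was 0.068 on the 75th percentile of probes well above background, 0 with quantile normalization and 0 by construction when centred on itself. Nr4a1 was -0.13 with quantile normalization, -0.21 with spike-ins, -0.058 with housekeeping centring and -0.12 with loess. Nr4a2 was 1.19 with normexp, 1.07 with spike-ins, 1.23 with housekeeping centring and 1.19 as the mean of probes. Nr4a3 was -1.71 with normexp, -3.09 with spike-ins and -2.93 with housekeeping centring. Beyond the common shift and the normexp offset, the cause of these moves was not tested. The 48 genes followed singly were the leading genes of both directions, the Nr4a genes, and Treg signature, Th2 and Tfh members past 2-fold. Of these, 47 kept their direction in all settings run on them, Nr4a1 being the exception. Of the 47 past 2-fold in the main setting, 43 stayed past it. Because these genes were chosen for large differences, their kept directions were largely set in advance, and every setting reused the same arrays. Foxp3 ranged from -4.38 to -3.37. Signal over background limits the dim side: genes near the lowest signals, such as Nr4a3 in the array labelled Nr4a-TKO, had smaller differences with normexp. No paired analysis was possible because each genotype had 1 array, and the slide could not be a block.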

Other observations

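The tests of activated and resting T cells, of the Foxp3 probe, of single Xist probes, of handling and of ER chaperones were chosen only after the results were seen, and the ATF4, ER chaperone, cholesterol, X escape and Treg-restricted lists were written after the leading genes were known. Values of the ATF4 and X escape members had not been seen when their tests were written. Several genes known as ATF4 targets were higher. Trib3 was higher by 4.29-fold in the array labelled Nr4a-TKO, Stc2 by 4.95-fold (3.30-fold with normexp), Pycr1, which makes proline, by 4.63-fold, Vldlr by 4.32-fold, Cebpb by 4.05-fold, Eif4ebp1 by 3.44-fold and Ddit3 by 2.98-fold. The aminoacyl-tRNA synthetase genes Cars, Aars and Gars were higher by 2.19-fold, 1.86-fold and 1.69-fold, and Aars by 1.15-fold as the mean of its probes. Slc1a5 was lower by 1.44-fold. Genes of cholesterol synthesis had a median of 0.26 (percentile 95.4), with 0 of 15 past 2-fold, and -0.02 with spike-ins as the centre.

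The higher Asns, Chac1 and Slc7a3 may belong to a response run by ATF4, a transcription factor active when amino acids are short or the ER is stressed. Over 33 measured ATF4 targets outside the 15 leading genes the median was 0.87 (95% interval 0.69 to 1.13), at percentile 100 of the matched random lists, and 14 were past 2-fold. The ER chaperone list, which also holds Xbp1 and Edem1, had a median of only 0.15 (95% interval -0.30 to 0.35). Of its 12 members 9 were higher by any amount and 3 lower. This argues against a response to ER stress that raises this set as a whole. ER stress that acts through ATF4 without raising this set stays open. Handling of the sorted cells stays open, since the TCR immediate-early median of -0.040 has an interval of -0.46 to 0.09 that includes 0. Genotype and sex remain open as sources and were not tested.

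Foxp3 was lower by 17.2-fold while the Treg signature without it had a median of -0.23, though Plagl1 and Gzmb also differed by 7.97-fold and 5.61-fold. Replacement by resting conventional CD4 T cells was not decided by the genes lower in Treg than in such cells. Their median was -0.38 with an interval of -0.88 to 0.21 that includes 0. Resting cells were assumed, not measured, to hold more of the naive and resting T cell genes. That list had a median of -0.56 with an interval of -1.28 to -0.16, with 13 of 16 members lower and 3 higher. For these 16 genes the values argue against such replacement, a reading made after they were known. Replacement by activated helper T cells stays open. Lrrc32, Gpr83, Ikzf2, Ikzf4 and Nrp1 had a median of -0.45, far from the -4.11 of Foxp3. What activated helper T cells express was assumed and not measured. The array has 1 Foxp3 probe, so a Foxp3 transcript altered at the probe cannot be told apart from a lower level. An effect of the genotype is a further open hypothesis, for which no replicate exists.

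The Xist signal may come from RNA of female cells in the sample labelled Nr4a-TKO. The 4 X genes that escape inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) had a median of 0.32, above 0 as such cells would give, but at the 91.8th percentile of random lists and 0.04 with spike-ins as the centre. Cross-hybridisation of a single probe is argued against by the 7 Xist probes that were each brighter by 2-fold or more. The Y-linked signal that remained may then reflect male and female cells in 1 sample, which the labels do not address. Without X and Y genes, 713 of the 740 higher and 690 of the 720 lower genes were left, and sex effects on other chromosomes were not tested.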
